A study of Homo sapiens with 6 samples.

How the data were processed

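RNA levels were compared between 3 libraries of the MCF7NSC control line and 3 libraries of the MCF7b variant, with group and replicate taken from the sample titles. Per the labels' protocols, cells grown in medium with 10% serum were moved to 2% serum 16 h before collection, received 15 to 30 µl of phosphate-buffered saline 1 h before collection, and were harvested in TRIzol. The submitters' processing notes name STAR 2.5.2a, HTSeq, DESeq and edgeR and the genome build hg38. They give no role, order or options, so the annotation, the use of strand and the treatment of reads that match several places are not given in the sources used here. Reads from overlapping genes, antisense genes and close paralogs cannot be separated with these values. Among genes named in the report, exons of MGP, CLDN7, LDLR and ANGPTL4 overlap genes on the other strand that held 0.168, 0.239, 0.322 and 0.423 times as many counts.

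The authors deposited raw counts, as whole numbers of reads per gene for each of the 6 libraries, and these counts are the only values used for levels and tests here. The table listed 46783 genes, of which 5560 had 0 counts in all libraries and 41223 had reads, and 0 rows named no gene. Of the gene identifiers, 45101 matched GENCODE release 29 (GRCh38), from which coordinates and gene types were taken, and 1682 did not. The authors also deposited a table of their own comparison with p-values and log2 fold changes from edgeR and DESeq2 for 41223 genes, which was used only to count shared calls. Its rank columns, deposited by the authors as a score per gene, were not used further; the combined one equalled the sum of the ranks of the single tools, to within less than 1, in 100% of the genes. Their log2 fold changes and those computed here correlated across genes at 0.99997.

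Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM scaling, the default filter on low counts (minimum count 10, applied with the group) and the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the 21012 genes that passed the filter, and genes with an adjusted p below 0.05 are called. The TMM factors lay between 0.992 and 1.01. Levels are CPM of the TMM-scaled library totals. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 4.72%, which is low and makes small differences pass the test. Where a group had 0 counts, the fold is a lower bound taken at 3 counts over the 3 libraries of that group; with 1 to 3 counts, the ratio is given with an exact 95% counting interval, also for named genes with few counts when a library is left out. The test was checked on simulated counts of this comparison for 21012 genes, with 50 genes changed at each size. It recovered 46% of the genes changed 1.25-fold, 74% at 1.5-fold, 98% at 2-fold and 100% at 4-fold. There were 15 false calls among 20812 unchanged genes, and as a share of all calls in the simulation these exceeded 0.05. The changed genes had a mean of at least 1 CPM and were balanced in direction. In the real data 54.0% of genes were called, so the check does not cover such broad change or lower genes.

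Before the data were examined, 24 gene lists were written from background knowledge and tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes. The alternatives were camera with an estimated correlation and fry, whose p asks whether the genes of a list move, on balance, one way and makes no comparison with other genes. Calls that held with the estimated correlation were those of the NFkB, extracellular matrix and bone marrow stroma lists. The matrix and stroma lists share genes, among them COL3A1, and had small median log2 fold changes (-0.0828 and -0.184). Several lists share genes, for example 8 of the dormancy genes are on another list.

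The named genes follow a rule fixed in advance. It took the 8 genes with the largest fold change each way among called genes with a mean of at least 1 CPM, no overlap between groups and a symbol, where clone-type names were treated as no symbol. It took of each list up to 3 called members with the largest change at that level, or 2 each way where the list moved both ways. It also took 10 genes whatever their result: LIFR, SOCS3, PTHLH, GLI2, ESR1, PGR, GREB1, CDH1, CXCR4 and CD44. Genes named only for an exon overlap and LINC00472 were chosen after their values were seen.

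The libraries differ in depth, from 22.6 to 51.9 M counts, and the MCF7NSC libraries were deeper on average (40.2 against 25.3 M). No libraries of a group agreed within sampling noise, which does not by itself show independent cultures. Each library counts as 1 replicate because the series design text gives each an experiment of its own. The replicates are cultures of 1 control line and 1 variant. P-values therefore measure scatter between cultures, not between lines of each kind. The alternatives tried were size factors of the DESeq2 kind, no filter on low counts, a filter at 1 CPM in 3 libraries, the replicate number as a term, leaving out each library in turn, DESeq2 1.42.0 and limma voom. Thinning all libraries to the lowest total was added after seeing the data. Positions, neighbors and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The tests of positions, windows and chromosome segments used the 12855 protein-coding genes with a mean of at least 1 CPM over the libraries. No genome sequence was used here.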

Results

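RNA was sequenced from MCF7 cells, an established human breast cancer line that carries the estrogen receptor, in 2 forms. The control, MCF7NSC, holds a non-silencing short hairpin RNA construct. The other form, MCF7b, is a variant of the line described as metastatic to bone. Each form gave 3 libraries, and per the series design text each replicate came from an experiment of its own. All cultures spent 16 h in medium with 2% serum and received phosphate-buffered saline, a vehicle, for the last 1 h before harvest. The deposited counts per gene summed to 45.9, 51.9 and 22.9 M (mega) in MCF7NSC replicates 1, 2 and 3, and to 22.6, 29.5 and 23.8 M in MCF7b. At this depth a total of 3 counts over the 3 libraries of a group, used as the floor, corresponded to 0.0398 CPM (counts scaled per M counts of the library) in MCF7b and 0.0248 CPM in MCF7NSC. Mitochondrial transcripts took 7.86%, 7.22% and 7.26% of the counts in MCF7NSC and 8.84%, 8.94% and 9.06% in MCF7b. MCF7NSC replicate 1 stood somewhat apart in its group: the mean chi-square of its counts per gene was 9.32 against replicate 2 and 8.68 against replicate 3, whereas replicates 2 and 3 gave 1.79 and the MCF7b comparisons 1.36 to 1.92. Levels below are means ± SD in CPM with n = 3 per group, fold changes are MCF7b over MCF7NSC, and errors of log2 fold changes are standard errors. The words rose, fell, higher and lower describe MCF7b relative to MCF7NSC. No parental line was analysed here, so the data do not show in which line a gene changed. Counting intervals and floors cover counting error only.

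The comparison asked how the transcriptome of the bone-metastatic variant differs from that of the control line. MCF7b had far lower levels of most NFkB target and inflammatory cytokine genes tested, and lower levels of many immediate early, antigen presentation and interleukin 6 family genes. Of these lists only the NFkB one kept its call with an estimated correlation between genes. Transcripts of the keratin KRT13, matrix Gla protein, the stanniocalcin STC2, the progesterone receptor and E-cadherin were higher. Of 21012 genes tested, 11342 (54.0%) passed an adjusted p of 0.05 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 5325 higher and 6017 lower in MCF7b. Most of these changes were small, since 58.9% of the called genes differed by less than 1.5-fold, and 845 genes were at least 2-fold higher and 1384 at least 2-fold lower. At 10-fold or more, 25 called genes with a mean of at least 1 CPM in MCF7b were higher. Another 128 with a mean of at least 1 CPM in MCF7NSC were lower. These 10-fold counts take genes at 0 counts in a group at their bounds. The first principal component, with 90.9% of the variance, separated the groups. Across genes, which are not independent replicates, log2 CPM correlated at 0.996 or more within groups and at 0.961 to 0.965 between them. With no filter on low counts, 1301 genes were at least 2-fold higher. In the authors' deposited table, edgeR called 12014 genes, of which 10494 were called here with the same sign and 0 with the opposite sign.

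**Figure D1:**
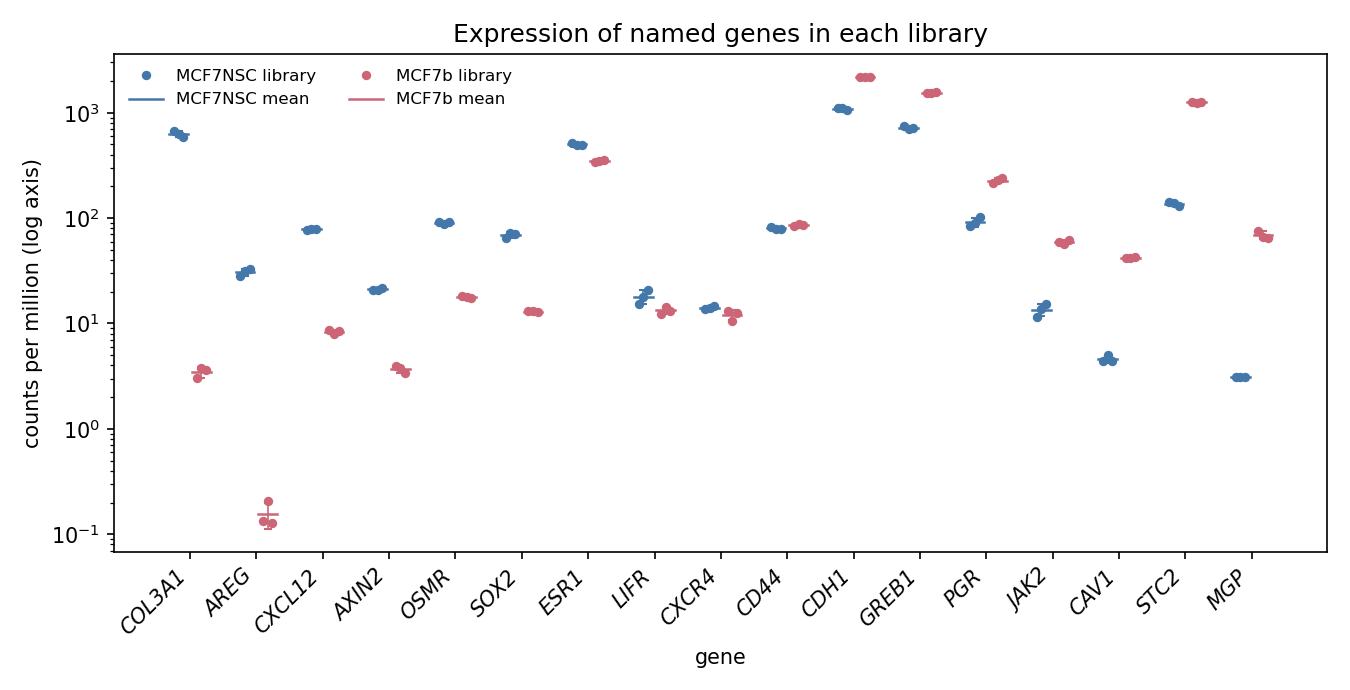
Expression of 17 named genes in each library, in CPM on a log axis, for MCF7NSC (blue) and MCF7b (red); points are libraries, horizontal lines group means and bars the SD (n = 3 per group). COL3A1 stands at 631 CPM in MCF7NSC and 3.48 CPM in MCF7b, STC2 at 137 and 1254 CPM, and CD44 at 80.0 and 86.2 CPM.

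Among genes higher in MCF7b, MGP, encoding the matrix Gla protein that inhibits calcification (chromosome 12, 14881181 to 14885926, GRCh38, GENCODE 29, minus strand), rose from 3.10 ± 0.0055 to 69.0 ± 5.78 CPM, a log2 fold change of 4.47 ± 0.08 (adjusted p = 6.66e-13, edgeR quasi-likelihood test, Benjamini-Hochberg). KRT13, a keratin of stratified epithelia (chromosome 17, 41500981 to 41505705), rose 57.3-fold, from 0.276 ± 0.216 to 13.0 ± 0.540 CPM. MSMB, which encodes a secreted protein of the prostate (chromosome 10, 46033307 to 46046269), rose 19.3-fold to 9.32 ± 0.284 CPM. SAGE1, a cancer-testis antigen gene (chromosome X, 135889205 to 135913061), had 0 counts in MCF7NSC and 2.49 ± 0.0965 CPM in MCF7b, at least 100.5-fold higher. DEFB118, a beta-defensin gene (chromosome 20, 31368618 to 31373923), also had 0 counts in MCF7NSC and 2.02 ± 0.238 CPM in MCF7b, at least 81.5-fold higher. ADAD2 had 3 counts in MCF7NSC against 176 in MCF7b, a ratio of 94.2 (95% counting interval 31.7 to 461). All 3 came from MCF7NSC replicate 1. Without it MCF7NSC had 0 counts and ADAD2 was at least 57.7-fold higher, and with any other library left out the ratio was 53.84 to 99.67. The long non-coding RNA LINC01168 rose 24.0-fold and the pseudogene CMAHP 21.4-fold. Exons of CMAHP overlap exons of CARMIL1 on the other strand, which held 17.0 times as many counts, and exons of ADAD2 overlap AC009123.1, which held 0.246 times as many. The sources used here do not give whether counting used strand, so the values of such overlapping genes are uncertain.

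The genes with the largest folds lower in MCF7b stood at 0 or near it there. LCN2, encoding the iron-binding secreted protein lipocalin (chromosome 9, 128149071 to 128153455), fell from 115 ± 3.70 to 0.0624 ± 0.0547 CPM, with 13825 counts in MCF7NSC and 5 in MCF7b (log2 fold change -10.68 ± 0.14, adjusted p = 1.09e-13, edgeR quasi-likelihood test, Benjamini-Hochberg). DACH1, a transcription factor gene (chromosome 13, 71437966 to 71867192), stood at 14.3 ± 0.616 CPM in MCF7NSC and at 0 counts in every MCF7b library, at least 358-fold lower. DIO2, the thyroid hormone activating deiodinase (chromosome 14, 80197527 to 80387757), was at least 225-fold lower and the zinc finger gene ZNF804A (chromosome 2, 184598366 to 184939492) at least 128-fold lower. The same holds for CXCL8, a neutrophil chemoattractant, at least 104-fold lower; for LTB, lymphotoxin beta, at least 96.2-fold lower; and for C8orf4, at least 79.4-fold lower. The feature with the largest bound was MIR30A, a microRNA gene in an intron of LINC00472 (chromosome 6, 71403551 to 71403621, minus strand), with 25.8 ± 1.58 CPM in MCF7NSC and 0 counts in MCF7b, at least 647-fold lower. Its host transcript LINC00472 was 5.72-fold lower (95% interval 3.93 to 8.34, from the standard error of the fit). Reads from the hairpin construct of MCF7NSC are a candidate source of the MIR30A counts. A lower level of the microRNA itself is therefore not established.

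The NFkB and inflammatory cytokine list had the largest median change of the 24 lists tested. Of its 21 measured members, 18 fell, 0 rose and 3 did not pass the test, and the counts adjusted over the list alone were the same. The median log2 fold change was -4.05, or -3.96 with the 6 members at 0 in MCF7b set at their bounds (camera adjusted p = 9.9e-36; adjusted p = 0.0265 with an estimated correlation). Besides LCN2 and CXCL8, the cytokine gene TNF fell from 6.56 ± 0.317 CPM to 3 counts in MCF7b, a ratio of 166 (95% counting interval 56.7 to 808). Of 24 measured interferon response genes, 15 fell, 0 rose and 9 did not pass the test; 16 fell when adjusted over the list alone. BST2, which tethers budding viruses, fell 7.87-fold to 0.945 ± 0.259 CPM, UBE2L6, an enzyme of ISG15 conjugation, 4.02-fold, and the ISG15 ligase HERC5 3.67-fold. The interferon list had a camera adjusted p of 0.00401, with an adjusted p = 0.292 with an estimated correlation. Antigen presentation genes fell in 13 of 17 cases and rose in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.000122; adjusted p = 0.28 with an estimated correlation). The immunoproteasome subunit PSMB8 fell 13.2-fold and the invariant chain CD74 6.28-fold, whereas HLA-DRB1 rose 1.90-fold and HLA-E 1.27-fold. PSMB8 rested on 11 MCF7b counts, its log2 fold change of -3.73 ran from -4.34 (without MCF7b replicate 1) to -3.32 (without MCF7b replicate 2) with a library left out, and its exons overlap those of PSMB9 on the other strand, which held 0.836 times as many counts. HLA genes resemble each other and can share reads, so their values are uncertain.

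**Figure D2:**
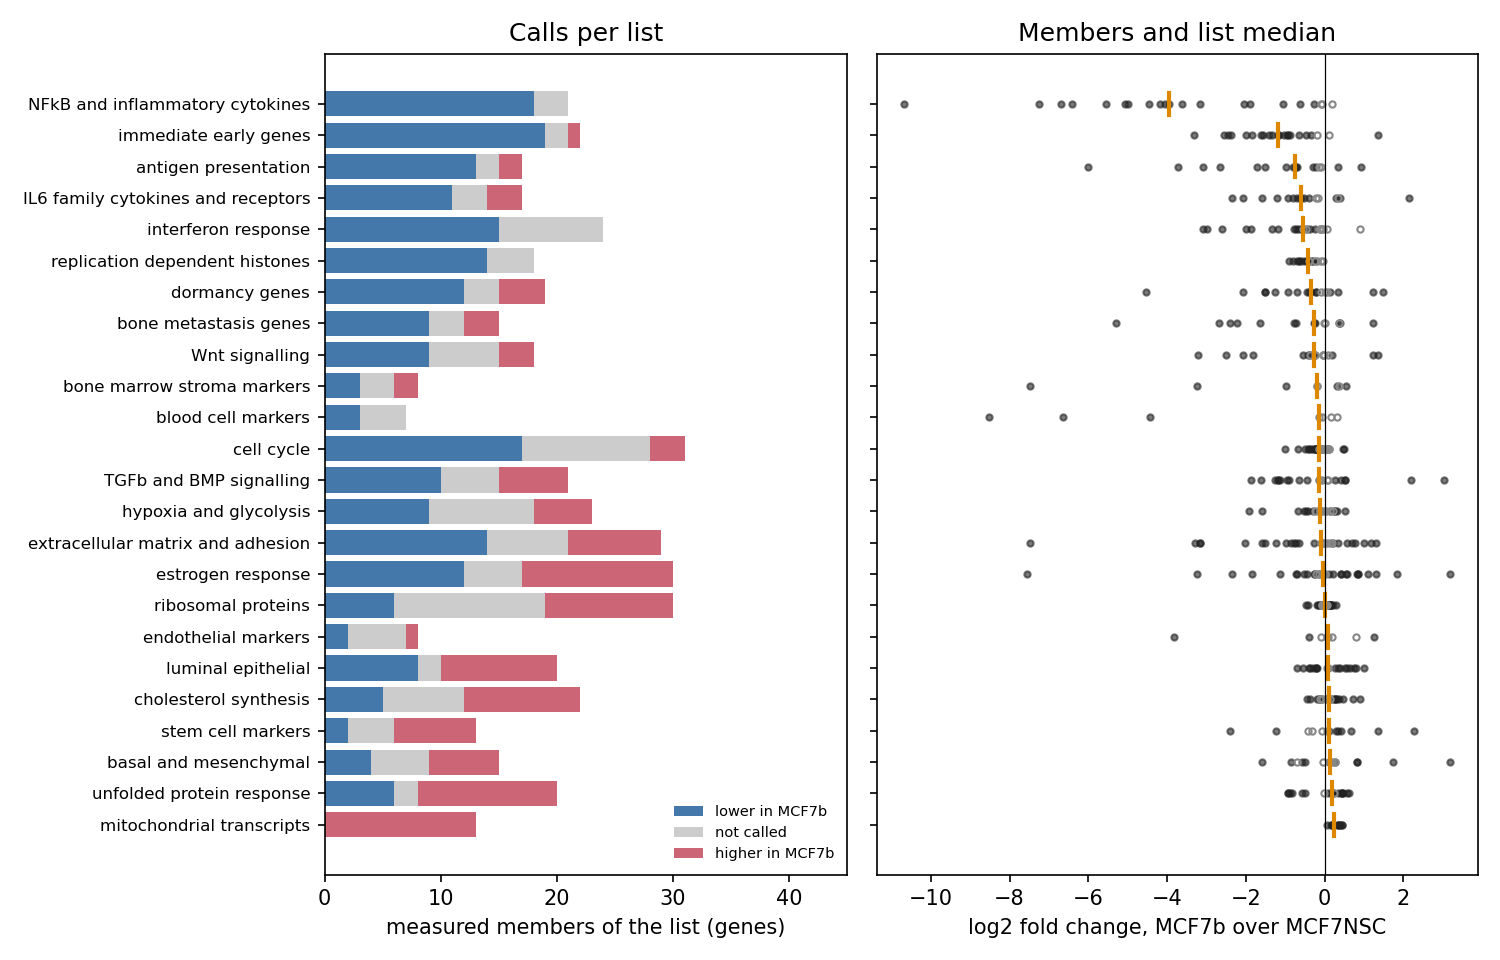
Calls and fold changes for the 24 gene lists. Left, the number of measured members lower in MCF7b (blue), not called (grey) and higher (red); right, the log2 fold change of each member (filled, called; open, not called; genes at 0 in one group at their bound) with the list median in orange. The NFkB list has its median at -3.96 and the mitochondrial transcripts have 13 of 13 members higher.

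Among cytokines of the interleukin 6 family and their receptors, 11 of 17 measured members fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00176; adjusted p = 0.115 with an estimated correlation). OSMR, the oncostatin M receptor (chromosome 5, 38845858 to 38945596), fell from 90.8 ± 1.73 to 17.9 ± 0.362 CPM, a log2 fold change of -2.34 ± 0.04. LIF, leukemia inhibitory factor, fell 4.20-fold. JAK2, the kinase that couples cytokine receptors to STAT proteins (chromosome 9, 4984390 to 5128183), rose 4.40-fold to 58.96 ± 2.504 CPM, and the cytokine IL11 rose 1.31-fold. LIFR, the receptor of leukemia inhibitory factor, which has been linked to tumor cell dormancy in bone, was 18.01 ± 2.83 CPM in MCF7NSC and 13.3 ± 1.07 CPM in MCF7b, a log2 fold change of -0.41 ± 0.10 (adjusted p = 0.00508, edgeR quasi-likelihood test, Benjamini-Hochberg). SOCS3, a feedback inhibitor of the pathway, fell 1.63-fold. Exons of OSMR overlap RICTOR on the other strand, which held 0.769 times as many counts, and exons of LIFR overlap LIFR-AS1, which held 0.274 times as many.

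Of 19 genes linked to tumor dormancy, 12 fell, 4 rose and 3 did not pass the test, with the same counts adjusted over the list alone. The camera adjusted p was 0.0353; it was adjusted p = 0.197 with an estimated correlation and adjusted p = 0.102 with a filter at 1 CPM. The transcription factor SOX9 fell from 37.7 ± 2.11 to 1.60 ± 0.541 CPM, a log2 fold change of -4.52 ± 0.13, and the angiomotin gene AMOT 2.83-fold. IGFBP5, an insulin-like growth factor binding protein, rose 2.80-fold, and the secreted Wnt inhibitor DKK1 rose from 122 ± 0.650 to 286 ± 5.09 CPM.

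Of 15 measured genes linked to bone metastasis, 9 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0208; adjusted p = 0.283 with an estimated correlation). PTHLH, encoding the parathyroid hormone-related protein that drives bone resorption (chromosome 12, 27958084 to 27972705), fell from 2.78 ± 0.0468 to 0.0652 ± 0.0638 CPM, a log2 fold change of -5.31 ± 0.33 (adjusted p = 4.27e-08, edgeR quasi-likelihood test, Benjamini-Hochberg). It rested on 5 MCF7b counts, 3 of them in replicate 3 and 2 in replicate 2. Without replicate 3 the ratio was 71.9 (95% counting interval 19.8 to 596) and without replicate 2 it was 42.6 (14.5 to 208), whereas without MCF7b replicate 1 the log2 fold change was -4.82. CSF1, the macrophage colony-stimulating factor, fell 6.46-fold to 1.58 ± 0.247 CPM. DKK1 and IL11 are the named members that rose. The chemokine receptor CXCR4 stood at 14.1 ± 0.621 and 12.03 ± 1.33 CPM, a log2 fold change of -0.23 ± 0.08 (adjusted p = 0.0294, edgeR quasi-likelihood test, Benjamini-Hochberg). That call was lost without MCF7NSC replicate 2 (adjusted p = 0.0582), MCF7NSC replicate 3 (0.0627) or MCF7b replicate 2 (0.169), and with DESeq2 (0.0713). GLI2, a hedgehog transcription factor upstream of PTHLH, had 13, 19 and 7 counts in MCF7NSC and 5, 9 and 3 in MCF7b, too few to be tested.

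Estrogen response genes moved both ways, 13 higher and 12 lower of 30, with the same counts adjusted over the list alone. The list median of -0.04 and mean of -0.24 differed in sign from the camera direction, which was up (adjusted p = 0.869). That direction was down with fry (adjusted p = 0.0944), with no filter on low counts (0.614) and without MCF7NSC replicate 2 (0.806). ESR1, the estrogen receptor alpha gene (chromosome 6, 151656691 to 152129619), fell from 503 ± 11.96 to 349.7 ± 10.1 CPM, a log2 fold change of -0.53 ± 0.03. Its targets PGR, the progesterone receptor (chromosome 11, 101029624 to 101130524), and GREB1 rose, PGR from 91.8 ± 8.86 to 227 ± 11.6 CPM and GREB1 from 722 ± 24.8 to 1557 ± 15.1 CPM. The secreted glycoprotein gene STC2 (chromosome 5, 173314713 to 173329503) rose from 137 ± 6.72 to 1254 ± 23.4 CPM, a log2 fold change of 3.19 ± 0.04 (adjusted p = 4.22e-14, edgeR quasi-likelihood test, Benjamini-Hochberg), and the potassium channel gene KCNK5 rose 3.60-fold. The epidermal growth factor receptor ligand AREG fell 188-fold, to 12 counts over the MCF7b libraries, and the chemokine CXCL12 fell 9.47-fold.

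Luminal epithelial genes rose in 10 and fell in 8 of 20 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.0208, up; adjusted p = 0.28 with an estimated correlation). CDH1, encoding E-cadherin (chromosome 16, 68737225 to 68835548), rose 1.99-fold, from 1093 ± 29.6 to 2181 ± 19.5 CPM, and the tight junction gene CLDN7 rose 1.74-fold. TJP3, another tight junction gene, fell 1.61-fold and the mucin gene MUC1 1.45-fold. Of 15 measured basal and mesenchymal genes, 6 rose and 4 fell, or 5 when adjusted over the list alone. The list's camera adjusted p was 0.0286, up, and adjusted p = 0.197 with an estimated correlation. Its call was lost without MCF7NSC replicate 1 (adjusted p = 0.106), without MCF7NSC replicate 3 (0.0506) and with no filter on low counts (0.0596). The caveolin genes CAV1 and CAV2, neighbors on chromosome 7, rose 9.08-fold and 3.34-fold, while the fibronectin gene FN1 fell 2.99-fold and EGFR 1.49-fold. CD44, a hyaluronan receptor, differed by 0.11 ± 0.04 on the log2 scale (adjusted p = 0.0303, edgeR quasi-likelihood test, Benjamini-Hochberg). Its call was lost without MCF7NSC replicate 2 (adjusted p = 0.123), MCF7NSC replicate 3 (0.0927), MCF7b replicate 2 (0.121) or MCF7b replicate 3 (0.0993), with DESeq2 (0.0587), with thinned counts (0.0577) and with no filter (0.24).

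In TGFb and BMP signalling, 10 of 21 measured genes fell and 6 rose, or 11 and 6 when adjusted over the list alone (camera adjusted p = 0.1). The list passed the threshold, downward, with no filter on low counts (adjusted p = 0.00922). ID1, a target of bone morphogenetic proteins, fell 3.65-fold and BMP7 fell from 642 ± 19.1 to 209 ± 4.26 CPM. The activin subunit genes INHBA and INHBB rose 8.18-fold and 4.62-fold. Wnt signalling genes fell in 9 and rose in 3 of 18 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.287). AXIN2, a feedback target of the pathway (chromosome 17, 65528563 to 65561647), fell 5.71-fold to 3.69 ± 0.262 CPM and the receptor FZD7 4.19-fold, while MYC rose 2.55-fold and DKK1 2.35-fold. Of 13 measured stem cell markers, 7 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.097), and the list passed the threshold without MCF7NSC replicate 1 (adjusted p = 0.0478). The drug efflux pump gene ABCG2 rose 4.84-fold, SOX2 fell from 69.3 ± 4.03 to 13.0 ± 0.188 CPM, and the integrin gene ITGA6 fell 2.36-fold.

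Of 29 measured extracellular matrix and adhesion genes, 14 fell and 8 rose, or 9 rose when adjusted over the list alone (camera adjusted p = 6.24e-09, down; adjusted p = 0.0265 with an estimated correlation). The median log2 fold change of the list was -0.0828 and its mean -0.738. COL3A1, the type III collagen gene (chromosome 2, 188974320 to 189012746), had the smallest p of all genes. It fell from 631 ± 37.2 to 3.48 ± 0.413 CPM, a log2 fold change of -7.49 ± 0.07 (adjusted p = 7.99e-15, edgeR quasi-likelihood test, Benjamini-Hochberg). The integrin gene ITGB8 fell 9.75-fold, and the collagen gene COL6A1 rose 2.27-fold. COL3A1 and CXCL12 are also on the list of bone marrow stroma markers, of which 8 of 18 were measured, 3 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.99e-10; adjusted p = 0.0265 with an estimated correlation). COL3A1 and COL1A1 are on both the matrix and the stroma list, so these calls are not independent. The stroma list had a median of -0.184 and a mean of -1.35. ACTA2 rose 1.47-fold and TAGLN 1.26-fold on that list, although the ACTA2 call was lost without MCF7b replicate 3 (adjusted p = 0.0505) and with DESeq2 (0.061), and the TAGLN call without MCF7NSC replicate 2 (0.0512). Exons of TAGLN overlap PCSK7, which held 7.02 times as many counts, and those of ACTA2 overlap FAS, which held 1.78 times as many.

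Immediate early genes, which growth signals and stress induce within minutes, fell in 19 of 22 cases and rose in 1, MYC, with the same counts adjusted over the list alone. The median log2 fold change was -1.17 (camera adjusted p = 9.42e-28; adjusted p = 0.0504 with an estimated correlation). EGR2 fell 10.0-fold, from 10.9 ± 0.899 to 1.08 ± 0.0352 CPM, and FOSB 5.90-fold.

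Cell cycle genes fell in 17 and rose in 3 of 31 cases, or 4 rose when adjusted over the list alone, with a median log2 fold change of -0.15 (camera adjusted p = 0.0693). The list passed the threshold without MCF7NSC replicate 1 (adjusted p = 0.00869), MCF7NSC replicate 3 (0.046) or MCF7b replicate 3 (0.0474), and with no filter on low counts (0.00246). CDC20, an activator of the anaphase-promoting complex (chromosome 1, 43358955 to 43363203), fell 2.01-fold; the 142 protein-coding genes with a mean of at least 1 CPM between 40000001 and 60000000 on that chromosome had a median log2 fold change of -0.57. UBE2C fell 1.59-fold. The kinetochore genes CENPE and CENPF rose 1.40-fold and 1.39-fold, but the CENPF call was lost without MCF7b replicate 3 (adjusted p = 0.0892). Both calls were lost with DESeq2 (adjusted p = 0.101 for CENPE and 0.0785 for CENPF). CENPE stood at 29.8, 32.0 and 50.9 CPM in MCF7b replicates 1, 2 and 3. Its log2 fold change of 0.49 ran from 0.21 to 0.62 with a library left out. Hypoxia and glycolysis genes fell in 9 and rose in 5 of 23 cases, or 10 and 6 when adjusted over the list alone (camera adjusted p = 0.102; 0.0161, down, with no filter on low counts). The oxygen sensor EGLN3 fell 3.79-fold and ANGPTL4 3.01-fold, while LDHA rose 1.24-fold and ADM 1.42-fold.

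Cholesterol synthesis genes rose in 10 and fell in 5 of 22 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.132). CYP51A1 rose 1.86-fold and MSMO1 1.64-fold, while LDLR, the low-density lipoprotein receptor, fell 1.30-fold. DHCR24 fell 1.37-fold and lies in the same 40000001 to 60000000 interval of chromosome 1 as CDC20. Genes of the unfolded protein response rose in 12 and fell in 6 of 20 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.512); their median of 0.20 and mean of -0.01 differed in sign. TRIB3 rose 1.53-fold and the chaperone gene DNAJB9 1.48-fold, whereas the stress-induced transcription factors DDIT3 and ATF3 each fell 1.89-fold. Exons of DDIT3 overlap MARS and those of DNAJB9 overlap THAP5, which held 23.1 and 2.74 times as many counts.

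Of 20 blood cell markers 7 passed the filter on low counts, and 3 of these fell while 4 did not pass the test, with the same counts adjusted over the list alone (camera adjusted p = 9.51e-05; adjusted p = 0.188 with an estimated correlation). The 3 were the calcium-binding protein genes S100A8 and S100A9 and the integrin gene ITGAM. S100A8 fell from 6.36 ± 0.476 CPM to 1 count in MCF7b, a ratio of 471 (95% counting interval 84.2 to 18613), and S100A9 from 21.6 ± 0.613 to 0.196 ± 0.167 CPM. The single S100A8 count was in MCF7b replicate 2, without which MCF7b had 0 counts and S100A8 was at least 97.67-fold lower. The S100A9 log2 fold change of -6.64 ran from -7.59 (without MCF7b replicate 2) to -6.23 (without MCF7b replicate 1) with a library left out. ITGAM had 359 counts in MCF7NSC and 10 in MCF7b, 9 of them in replicate 3. Without that library the ratio was 153.7 (95% counting interval 27.4 to 6087), and with any other left out the log2 fold change of -4.44 ran from -4.49 to -3.75 (without MCF7b replicate 2). Of 12 endothelial markers 8 passed the filter, and 1 of these rose while 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.869, up, against a mean of -0.24; down with fry, 0.76, and with no filter on low counts, 0.983). ERG rose 2.37-fold to 1.77 ± 0.497 CPM and EMCN fell 1.32-fold.

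The 13 mitochondrial transcripts all rose, with the same count adjusted over the list alone, by a median log2 fold change of 0.23 (camera adjusted p = 0.00124; adjusted p = 0.28 with an estimated correlation), alongside the higher mitochondrial share of counts in the MCF7b libraries. MT-ND4 rose 1.36-fold, MT-ND6 1.32-fold and MT-ND4L, which overlaps MT-ND4, 1.37-fold. Of 18 measured replication-dependent histone genes, 14 fell and 0 rose, or 15 fell when adjusted over the list alone (camera adjusted p = 0.0208; adjusted p = 0.292 with an estimated correlation). HIST1H1B fell 1.89-fold, HIST1H2AC 1.74-fold and HIST1H2BH 1.62-fold; these genes have near-identical copies that can share reads. Ribosomal protein genes rose in 11 and fell in 6 of 30 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.719, up; down with no filter on low counts, 0.95). RPL13 rose 1.23-fold and RPS23 1.154-fold. RPL11 and RPS8 fell 1.39-fold and 1.34-fold; both lie in the first 60 Mb of chromosome 1, where the 525 protein-coding genes with a mean of at least 1 CPM had a median log2 fold change of -0.61.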

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

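All alternatives were set in advance except thinning to equal depth, which was chosen after seeing the data. In no setting did a gene called both there and in the main analysis have opposite signs. Genes called only in another setting were not compared in sign. Calls numbered 11375 with the other size factors, 12360 with no filter, 10414 with the filter at 1 CPM, 9719 with DESeq2, 11234 with limma voom and 10624 after thinning. Of the main calls, 85.1% (without MCF7b replicate 2) to 98.3% (limma voom) were kept with the same sign, and lower genes made up 50.9% to 56.5% of calls. The replicate block gave 11374 calls and kept 97.51% of the main ones, and it changed no list. Deviations of same-numbered libraries correlated at 0.107, 0.0062 and 0.062, and not every library correlated best with its own number, so the numbers were not taken to pair the samples. Leaving out each library gave 4547 to 5901 genes higher and 5366 to 6160 lower, 870 to 1051 at least 2-fold higher and 1336 to 1535 at least 2-fold lower.

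With no filter on low counts, 1301 genes were at least 2-fold higher, since more low genes were tested. In the same setting the direction turned for estrogen response (adjusted p = 0.614), endothelial markers (0.983) and ribosomal proteins (0.95). Basal and mesenchymal genes lost their call (0.0596), and cell cycle (0.00246), hypoxia (0.0161) and TGFb and BMP (0.00922) gained one. The filter at 1 CPM ended the dormancy call (0.102). An estimated correlation in camera ended those of dormancy (0.197), bone metastasis (0.283), IL6 family (0.115), luminal (0.28), basal (0.197), interferon (0.292), antigen presentation (0.28), immediate early (0.0504), blood cell (0.188), mitochondrial (0.28) and histone lists (0.292). Fry, which asks another question, turned estrogen response (0.0944) and endothelial markers (0.76) and passed cell cycle (0.000989), hypoxia (0.00164), cholesterol synthesis (0.000348), unfolded protein response (0.0236), TGFb and BMP (4.66e-05), Wnt (0.000979) and stem cell lists (4.66e-05). With a library left out, adjusted p ran from 0.0244 to 0.106 for basal and mesenchymal, 0.00869 to 0.118 for cell cycle, 0.0478 to 0.152 for stem cell and 0.706 to 0.876 for estrogen response genes, the last of which turned without MCF7NSC replicate 2 (0.806). Beyond the settings named, the cause was not tested. Of the named genes, CD44, CXCR4, CENPE, CENPF, ACTA2 and TAGLN lost their call in some setting. Depth limits genes with a few counts in a group, whose folds are bounds or wide intervals.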

Other observations

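The tests of MIR30A, the 20 Mb windows, the chromosome 1 segment, the list medians relative to windows, the other-cell marker ratios, the calls of the blood, stroma and basal markers and the genes of the next paragraph were chosen after the result was seen; the other tests were set before.

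Near SAGE1 on chromosome X, of 5 listed genes of the cancer-testis family CT45, 3 passed the filter on low counts and all 3 were higher in MCF7b. The others, CT45A3 and the pseudogene CT45A11P, had 0 and 12 counts in MCF7NSC and 1 and 4 in MCF7b. CT45A10 (135881063 to 135889086) had 1 count in MCF7NSC and 147 in MCF7b, a ratio of 236 (95% counting interval 41.7 to 9390). CT45A1 had 2 and 52 counts, a ratio of 41.8 (10.996 to 354), and CT45A5 had 0 and 36 counts, at least 19.4-fold higher. These paralogs can share reads, so the counts of single members are uncertain. In all, 11 genes were read at 1 CPM or more in each MCF7NSC library and had 0 counts in MCF7b. They include, besides the genes named in the report, CCL20 (1.87 ± 0.137 CPM, SD, n = 3), SAA1 (1.26 ± 0.118 CPM), GPR139 (1.39 ± 0.189 CPM) and LINC00284 (1.17 ± 0.153 CPM). The reverse held for 2 genes, DEFB118 and SAGE1.

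Of the 10 splits of the 6 libraries into 3 and 3, only the real one gave 11342 called genes. The highest of the others gave 0. Each other split mixes both lines in its groups, so a large difference between the lines alone leaves few calls. The counts thus decide nothing about chance, and 10 splits are too few for a share under 0.05.

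Neighboring genes moved together: the log2 fold changes of adjacent protein-coding genes correlated at 0.242 over the 12855 with a mean of at least 1 CPM, above the 0.0311 that was the highest of 1000 shuffles of positions, which argues against chance placement. After trends on GC content and length of each gene's longest transcript were removed the correlation was 0.232, so those transcript traits do not account for it. No genome sequence was used, so a bias on the GC content of the surrounding region stays open. In the first 60 Mb of chromosome 1, 525 genes had a median log2 fold change of -0.61 (quartiles -0.83 and -0.40), and 93.5% were lower in MCF7b against 51.1% of the other genes. The odd-gene median of a 5 Mb window predicted the even-gene median of the next window (r = 0.522), so a copy number difference over large segments is a candidate explanation. The loss of 1 of 3 copies would give -0.58, but DNA was not measured here, and shared regulation of neighbors over long distances stays open.

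That segment held 463 genes called lower, 9.88% of such calls among these genes, against 4.08% of the genes. Other 20 Mb windows with medians beyond 0.3 on the log2 scale were the 60000001 to 80000000 window of chromosome 1 (-0.35), the first of chromosome 7 (-0.37), the 40000001 to 60000000 windows of chromosomes 3 (-0.35) and 14 (0.38), the 60000001 to 80000000 window of chromosome 9 (0.37) and the 120000001 to 140000000 window of chromosome 7 (0.32). On chromosome 7, every window from 60000001 to 160000000 had a median of 0.23 to 0.32, with 75.4% to 85.1% of genes higher. CAV1 and CAV2 lie in this stretch. Of 152 windows tested against 10000 random draws of genes, 20 were lower and 23 higher after Benjamini-Hochberg adjustment, and 0.0001 was the smallest p the draws can give. This window size replaced an earlier one of 5 Mb, at which comparison with shuffled positions had singled out no window. Without the first 60 Mb of chromosome 1 the correlation of adjacent genes was 0.215. Measured against their own windows, list medians moved by between -0.22 and 0.20. That of the NFkB list became -3.97. The 5 lists that moved most were extracellular matrix (-0.0828 to -0.307), TGFb and BMP (-0.142 to -0.358), Wnt (-0.261 to -0.0645), bone metastasis (-0.266 to -0.462) and bone marrow stroma (-0.184 to 0.006). The others moved by 0.137 or less, which for small medians was a large part, as for stem cell markers (0.107 to 0.0516).

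The low levels of NFkB list transcripts in MCF7b were weighed against technical causes. The blood and stromal genes PTPRC, VIM, TYROBP and LYZ together reached at most 0.00403 of the NFKBIA level in an MCF7NSC library, where NFKBIA stood at 345 to 355 CPM. NFKBIA still stood at 93.0 to 97.1 CPM in MCF7b, so that ratio says little about list members of a few CPM. The sum of these blood and stromal genes was 1.31 to 1.43 CPM in MCF7NSC libraries and 1.13 to 1.40 CPM in MCF7b libraries. PTPRC and TYROBP had 0 counts in MCF7NSC, and COL1A2, SPARC, DCN and POSTN together reached at most 0.000221 of the COL3A1 level. Of the 38 listed blood and stroma markers 6 were lower in MCF7b (S100A8, S100A9, ITGAM, COL1A1, COL3A1 and CXCL12), 2 were higher, 7 did not pass the test and 23 were not tested for lack of counts. COL3A1 fell from 631 to 3.48 CPM and CXCL12 from 78.6 to 8.32 CPM. The markers that fell thus came without other abundant genes of such cells, which argues against blood or stromal cells in the control cultures. Cells of types on none of the lists were not tested and stay open. Of the basal epithelial markers, KRT5, KRT14 and KRT17 did not pass the filter on low counts, and TP63 stood at 0.854 CPM in MCF7NSC and 0.470 CPM in MCF7b. Within 1 Mb of the 18 called members, which lie on 9 chromosomes, were 407 genes with a mean of at least 1 CPM. Their median log2 fold change was -0.0488. The 95% bootstrap interval, which treated neighbors as independent, was -0.0874 to -0.00598. This argues against a loss that covers most of these neighboring genes. Neighbors were pooled and no median per member was taken, so the share of members this holds for is unknown. The pooled median cannot show a loss at a few places or of a member gene alone, so these stay open. As a hypothesis, NFkB activity may be lower in MCF7b or raised in the control, and the data do not separate these, because no parental line was analysed here.

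MIR30A reads came from MCF7NSC alone, 3153 in all, against 2 there for MIR30C2 in the same host. The host transcript LINC00472 fell by a factor whose upper 95% limit was 8.34, far below the bound of 647 for MIR30A, which argues against lower transcription of the shared locus as the whole cause. Hairpin constructs are often built in a microRNA 30 backbone, so reads from the construct are a candidate source; the labels do not name the backbone or say whether MCF7b carries it. LINC00472 was at most 0.0584 of the MIR30A level in an MCF7NSC library, as such a source needs, but that limit was set with the values known, the host itself fell, and the construct cannot be told apart from the line. An earlier form of the test, on all genes within 100 kb, decided nothing (ratio 2.38).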
